A study of Homo sapiens with 18 samples.

How the data were processed

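RNA was sequenced from primary human umbilical vein endothelial cells (HUVECs) of 18 wells, 6 in each of 3 groups: BMDM-free, naive BMDM (mouse bone marrow-derived macrophages in the top compartment of the transwell) and CYR61 BMDM (the same cells treated with CYR61 before). Per the labels' protocols, complementary DNA was made with a kit for low RNA input and sequenced as paired ends; whether counting used strand is not given in the sources used here. The authors deposited estimated counts per Ensembl gene, per the file headers and the values, some of which are not whole; they are not normalized. DRAGEN is named in the submitters' processing notes without a role or version; the aligner, genome build and annotation are not given in the sources used here. The authors also deposited a table for each of the 3 comparisons with a log2 fold change, a p-value and an adjusted p-value per gene, whose column names, per the file headers, are those of limma output, and log2 values per library. The authors' log2 values differed from log2 CPM computed here from the counts by a median of 0.00959. The authors' p-values were used to count their calls and, for LPXN and MMP1, are printed as deposited. Columns were matched to wells by the sample name in the labels' descriptions.

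The count table had 60871 rows. Rows that repeated an Ensembl gene with the same values were reduced to 1, which left 60671 genes, and the estimated counts were rounded to whole numbers. Gene symbols were those of the deposited count table. Coordinates, overlapping genes and the length and GC content of transcripts (the median over a gene's transcripts) came from the GENCODE 29 annotation, matched by Ensembl identifier. Since the use of strand is not given, it is not known whether overlapping genes on opposite strands were told apart. The total counts of 21.8 M to 29.9 M per library set the precision of low genes. Pairs of libraries within a group differed by more than sampling noise in all 45 pairs (chi-square per degree of freedom 6.37 to 54.1), so no library was taken for a copy of another. Some pairs were much closer than the rest. Naive BMDM replicates 5 and 6 had 6.37 with each other and 40.4 to 53.2 with the others of their group. BMDM-free replicates 1 and 2 had 7.62 with each other and 27 to 54.1 with the others. Close pairs occurred among CYR61 BMDM libraries too, such as replicates 2 and 6 (7.46) and replicates 4 and 5 (8.32). Naive BMDM replicates 1 to 4 had 8.46 to 12.0 with each other. The tests treat all libraries of a group as independent replicates, which such pairs may not be.

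Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, the filter of filterByExpr, a robust quasi-likelihood fit of 3 group means to all 18 libraries, and two-sided tests with Benjamini-Hochberg adjustment over the 15529 genes tested. A gene was called at an adjusted p under 0.05. Values per group are CPM from TMM-scaled library sizes, as mean ± SD of 6 libraries, and log2 fold changes are given ± SE. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with an estimated correlation between genes, adjusted over the lists within a comparison. There were 33 lists with 682 distinct symbols, of which 1, RIGI, was not matched; the last 4 lists are markers of macrophages, fibroblasts and smooth muscle, epithelium and lymphatic endothelium. The design, the lists, most alternatives and the rule for named genes were chosen before the data were examined. That rule takes the 10 called genes with the largest increase and the 10 with the largest decrease among those with at least 5 CPM, or the 5 with the smallest p where none was called. It adds up to 4 members with the smallest p of each list described, and always CCN1, VCAM1, ICAM1, SELE, CXCL8, CCL2, VEGFA, KDR, NOS3, CDH5, PECAM1 and VWF. Which lists to describe, and the exact permutation tests of list means over the 924 assignments of 6 and 6 libraries, were chosen after seeing the results. The smallest p such a permutation can give is 0.0022, so once adjusted over many lists a list passes only if several lie near that value.

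Alternatives were RLE size factors, library size only, no filter beyond a total above 0, a stricter filter of 5 CPM in 6 libraries, DESeq2 1.42.0, limma voom with sample quality weights, only the 12 libraries compared, the replicate number as a block, each library left out in turn, and an absolute log2 fold change of at least 1. For lists they were a preset correlation of 0.01 and fry. Chosen after seeing the data were a GC correction, limma voom without weights or with the GC correction, and fits without naive BMDM replicates 5 and 6, alone or together with CYR61 BMDM replicate 1 or replicates 1 and 2. The GC correction fitted, in each library, a lowess curve with a span of 0.3 to the deviation of genes with a mean log2 CPM of at least 2 on GC content, and used the curve as an offset. No column of samples was left unmapped (0 columns).

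The tests were checked on simulated counts with 50 genes changed at each fold. In edgeR 16%, 60%, 74% and 98% of genes changed 1.25, 1.5, 2 and 4 times were called in the setting of naive BMDM against BMDM-free wells (15239 genes), with 3 unchanged genes called. The shares were 18%, 54%, 64% and 88% for CYR61 against naive BMDMs (15255 genes, 6 unchanged called) and 20%, 54%, 68% and 92% for CYR61 BMDM against BMDM-free wells (15209 genes, 3 unchanged called). These counts were simulated without a GC trend. With the libraries' GC trend added, edgeR called 38 unchanged genes among 152 calls for CYR61 BMDM against BMDM-free wells, and 3 among 124 with the GC correction (15250 genes). The correction lowered no such count for naive BMDM against BMDM-free wells (10 unchanged genes called without it, 12 with it) and hardly for CYR61 against naive BMDMs (7 and 6). On counts with this trend and no changed genes, edgeR without the correction called 0 to 1 genes for CYR61 BMDM against BMDM-free wells and 0 in the other comparisons over 5 simulations. All these counts were drawn with the spread estimated before the correction, which already holds the trend. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.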

Results

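Gene expression was measured by RNA sequencing in primary human umbilical vein endothelial cells (HUVECs), which line the vein of the umbilical cord. The cells grew in the bottom compartment of transwell plates, where a membrane with pores of 0.4 µm separates them from whatever is in the top compartment. The top compartment held no cells (BMDM-free wells, n = 6), mouse bone marrow-derived macrophages without further treatment (naive BMDMs, n = 6), or BMDMs that had been treated with CYR61 at 0.5 µg/ml for 24 h (CYR61 BMDMs, n = 6). CYR61 is a secreted protein of the extracellular matrix, encoded in the human genome by CCN1. The HUVECs were harvested after 24 h beside the top compartment. Total counts per library lay between 21.8 M and 29.9 M, with group means of 26.3 ± 3.09 M for BMDM-free wells, 27.0 ± 2.91 M for naive BMDMs and 26.1 ± 2.26 M for CYR61 BMDMs (SD, n = 6). The labels describe the libraries of a group as separate wells and do not say whether the wells came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical. The design gives 3 comparisons, over 15529 genes.

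The HUVECs of all groups expressed the genes that mark endothelial cells. PECAM1, an adhesion molecule of endothelial junctions, stood at 941 ± 47.3 CPM (normalised read count, scaled to library size) in BMDM-free wells, 951 ± 38.2 CPM with naive BMDMs and 990 ± 31.2 CPM with CYR61 BMDMs (SD, n = 6). CDH5, the cadherin of endothelial junctions, stood at 181 ± 12.2, 186 ± 10.2 and 195 ± 13.9 CPM in the same order. CCN1 itself stood at 124 ± 6.23, 120 ± 5.97 and 121 ± 7.94 CPM. SELE, the adhesion molecule E-selectin, had 129 counts over the 18 libraries and at most 20 in any of them, and was not tested. VCAM1, VEGFA and ICAM1 were tested but also low, with 569, 641 and 1194 counts over the 18 libraries. They had at most 50, 45 and 123 counts in any library, so their log2 fold changes below rest on few reads.

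The libraries also differed in a property of the reads. Within each library, the deviation of genes from their mean over the 18 libraries followed the GC content of their transcripts, with a Spearman's rho across genes between -0.703 and 0.723; genes are not independent replicates. The group means of rho were -0.323 ± 0.320 in BMDM-free wells, -0.138 ± 0.666 with naive BMDMs and 0.364 ± 0.427 with CYR61 BMDMs (SD, n = 6). Among the naive BMDM libraries, replicates 5 and 6 had a rho of 0.708 and 0.723, against -0.692 to -0.433 in the other 4. CYR61 BMDM replicate 3 had -0.458, against 0.314 to 0.674 in the other 5. The difference between CYR61 BMDM and BMDM-free libraries was 0.687 (exact two-sided permutation p = 0.0152; adjusted p = 0.182 over 12 tests of library properties). The differences of 0.186 between naive BMDM and BMDM-free libraries and of 0.501 between CYR61 and naive BMDM libraries had exact permutation p of 0.548 and 0.195 (adjusted p = 0.730 and 0.670).

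**Figure D1:**
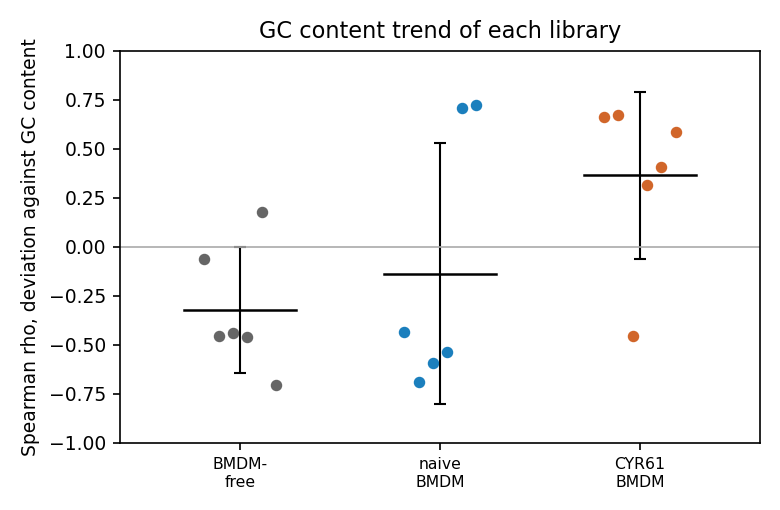
Spearman's rho across genes between a gene's deviation from its mean over the 18 libraries and the GC content of its transcripts, for each library (points) of the 3 groups on the horizontal axis, with group means and SD. Naive BMDM replicates 5 and 6 sit at 0.708 and 0.723, above the other 4 naive BMDM libraries, and CYR61 BMDM replicate 3 sits at -0.458, below the other 5 of its group.

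The first comparison asked how HUVEC expression with naive macrophages in the top compartment differed from that in BMDM-free wells. Genes of cholesterol synthesis were lower as a group beside naive BMDMs. Of the 23 members of this list that were tested, 19 had a log2 fold change below 0 and 4 above 0. HMGCS1, the synthase that makes HMG-CoA for the mevalonate pathway, stood at 44.4 ± 4.67 CPM in BMDM-free wells and 32.2 ± 5.16 CPM with naive BMDMs (SD, n = 6; log2 fold change -0.46 ± 0.0973, SE). The locus of HMGCS1 overlaps AC114947.2 on the opposite strand, so its counts are uncertain. INSIG1, which holds the sterol sensor SCAP in the endoplasmic reticulum, stood at 18.8 ± 2.20 and 13.0 ± 2.11 CPM (-0.53 ± 0.112). SCD, the desaturase that makes monounsaturated fatty acids, stood at 240 ± 26.8 and 190 ± 13.1 CPM (-0.34 ± 0.0705).

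The cholesterol synthesis list was called lower against all other genes (camera of limma, adjusted p = 1.52e-04 with an estimated correlation). None of its members passed over all genes tested, and 7 were lower when adjusted over the list alone. Beside HMGCS1 and INSIG1, the members with the smallest p were MSMO1, a methylsterol monooxygenase (log2 fold change -0.37), and IDI1, an isomerase of the mevalonate pathway (-0.28). The list's mean over its members was 5.43 ± 0.0559 log2 CPM in BMDM-free and 5.27 ± 0.0663 with naive BMDM libraries (SD, n = 6; exact permutation p = 0.00433, adjusted p = 0.107 over 99 such tests of 33 lists in 3 comparisons). The list of fatty acid genes and targets of the sterol receptor LXR was also called lower (adjusted p = 0.00660), with 16 of 19 members below 0. Adjusted over the list alone, SCD and LPCAT3, an enzyme that remodels phospholipids (-0.29), were lower and ANGPTL4, an inhibitor of lipoprotein lipase (0.86), was higher, while PLIN2, a coat protein of lipid droplets, stood at 0.19. IDI1, LPCAT3 and ANGPTL4 overlap genes on the opposite strand. The call of the fatty acid and LXR list was lost with the stricter filter on low counts (adjusted p = 0.336), without BMDM-free replicate 5 (0.0514) and without naive BMDM replicate 3 (0.0531). With each library's GC trend removed, which was added after seeing the data, both lists stayed called (adjusted p = 1.37e-04 and 0.00130).

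**Figure D2:**
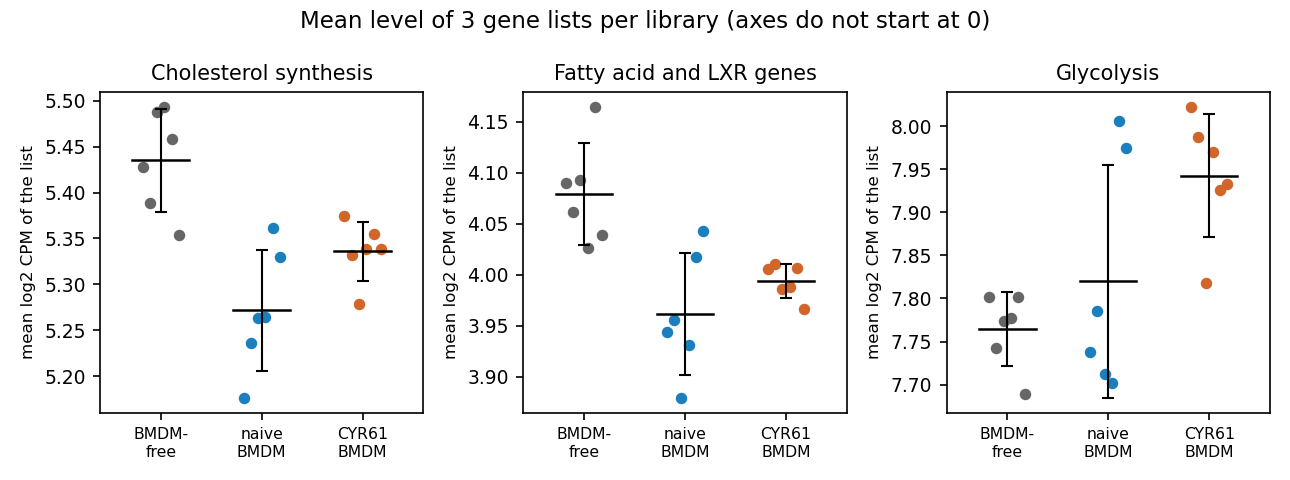
Mean log2 CPM over the members of the cholesterol synthesis, fatty acid and LXR, and glycolysis lists in each library (points), with group means and SD, for the 3 groups on the horizontal axis. The cholesterol synthesis mean is 5.43 in BMDM-free libraries and 5.27 in naive BMDM libraries.

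No single gene was called between naive BMDM and BMDM-free wells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (0 of 15529 genes; 701 had an unadjusted p under 0.05). DESeq2 called 6 genes, LPXN higher and ABI3BP, SCD, INSIG1, HMGCS1 and, named after its value was seen, PDIA3 lower. limma voom with sample quality weights called LPXN and MMP1 higher, and the authors' deposited table called the same 2 genes, LPXN (log2 fold change 0.45) and MMP1 (0.25), both higher with an adjusted p of 0.0243. The 5 genes with the smallest p were LPXN, ABI3BP, SCD, INSIG1 and HMGCS1, and none passed. LPXN, a paxillin-related protein of focal adhesions, stood at 19.4 ± 2.06 CPM in BMDM-free wells and 26.8 ± 1.92 CPM with naive BMDMs (0.46 ± 0.0854, adjusted p = 0.175), and all 6 naive BMDM libraries lay above every BMDM-free library. ABI3BP, a protein of the extracellular matrix, stood at 19.3 ± 2.46 and 12.7 ± 2.34 CPM (-0.60 ± 0.115, adjusted p = 0.175), with 5 of 6 naive BMDM libraries below every BMDM-free library; ABI3BP, PDIA3 and STAB1 overlap other annotated genes. SCD, INSIG1 and HMGCS1 had an adjusted p of 0.218 each, and all 6 naive BMDM libraries lay below every BMDM-free library for each of them. With the GC trend removed, 13 genes were called, 9 lower and 4 higher, among them these 5; the 4 higher were LPXN, MMP1, STAB1 and CDCP1, the last pair named after their values were seen. With naive BMDM replicates 5 and 6 left out, edgeR called 0 genes, and LPXN and MPZL2, the latter named after its value was seen, with the GC trend removed as well. Without naive BMDM replicate 3, ABI3BP was called lower. In the GENCODE 29 annotation HMGCS1 (ENSG00000112972) lies on chromosome 5 from 43289395 to 43313512, and LPXN (ENSG00000110031) on chromosome 11 from 58526871 to 58578220.

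**Figure D3:**
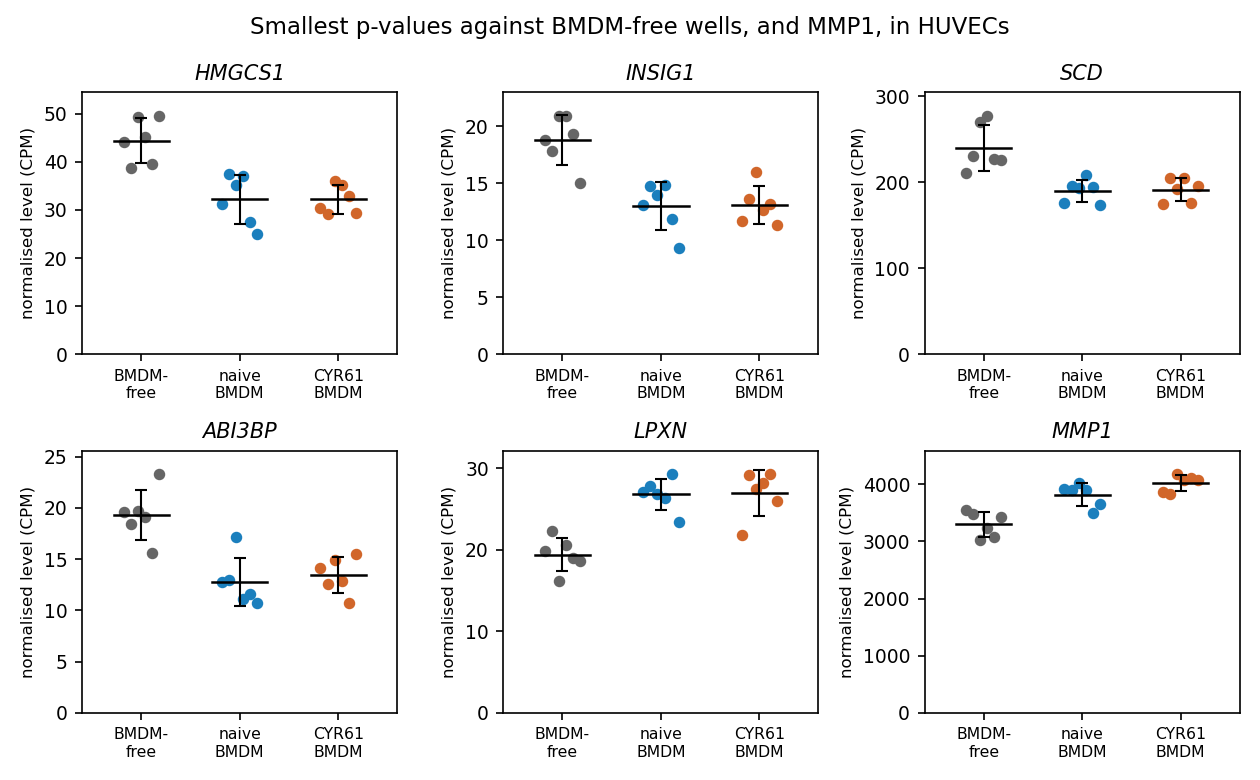
CPM of HMGCS1, INSIG1, SCD, ABI3BP, LPXN and MMP1 in each library (points) of the 3 groups on the horizontal axis, with group means and SD. LPXN rests at 19.4 CPM in BMDM-free libraries and 26.8 CPM in naive BMDM libraries, without overlap.

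Inflammatory genes did not pass as a group beside naive BMDMs. Of the 23 tested targets of NF-kB, the transcription factor of the inflammatory response, 20 had a log2 fold change above 0, and the list had an adjusted p of 0.0684 in camera. Adjusted over the list alone, IL1A, a pro-inflammatory cytokine (0.58), and NFKB2, a subunit of NF-kB (0.80), were higher; CSF3 stood at 0.32 and CCL2, a chemokine for monocytes, at 0.22. In the list of amino acid response genes that depend on ATF4, 19 of 26 members lay above 0 (adjusted p = 0.141) and 0 passed adjusted over the list alone. Its members with the smallest p were CHAC1, which degrades glutathione (0.38), the cystine transporter SLC7A11 (-0.22), GPT2 (0.33) and ALDH1L2 (0.39). The proteases and their inhibitors had an adjusted p of 0.163, and MMP1, an interstitial collagenase (0.21), was higher adjusted over the list alone. MMP1, SLC7A11 and ALDH1L2 overlap genes on the opposite strand, and strand was not given, so their counts are uncertain.

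Markers of other cell types gave no call in this comparison. Of the macrophage markers, 6 were tested and 5 lay above 0 (adjusted p = 0.447), with CTSS at 0.21, LAPTM5 at 0.09, LST1 at 0.39 and CD68 at -0.04. The adjusted p was 0.875 for fibroblast and smooth muscle markers, 0.738 for epithelial markers and 0.738 for lymphatic endothelial markers. The median over the fibroblast and smooth muscle markers was 0.06 while the test pointed down. The always named genes did not pass either: VCAM1 stood at 0.30, ICAM1 at 0.36, CXCL8 at 0.02, VEGFA at 0.08, KDR at 0.02, NOS3 at 0.12, CDH5 at 0.04, PECAM1 at 0.01, VWF at 0.14 and CCN1 at -0.05. The signs of CXCL8, KDR and PECAM1 turned when libraries were scaled by their size only. That of NOS3 turned with the GC trend removed, and that of VWF in voom with quality weights. CD68, LAPTM5, LST1, ICAM1, VEGFA, KDR, NOS3, PECAM1 and VWF overlap other annotated genes.

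The second comparison set CYR61-treated against naive macrophages, groups that by their labels differ in the treatment of the macrophages. Genes of glycolysis had higher means beside CYR61 BMDMs without passing the tests: 18 of the 20 tested members lay above 0. PKM, the pyruvate kinase, stood at 2009 ± 270 CPM with naive BMDMs and 2415 ± 201 CPM with CYR61 BMDMs (SD, n = 6; log2 fold change 0.27 ± 0.0721). TPI1, the triosephosphate isomerase, stood at 3191 ± 292 and 3773 ± 162 CPM (0.24 ± 0.0691), and its locus overlaps SPSB2 on the opposite strand. FEN1, the nuclease that processes DNA flaps in replication, stood at 151 ± 13.4 and 180 ± 8.02 CPM (0.25 ± 0.0621), with all 6 CYR61 BMDM libraries above every naive BMDM library.

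No gene was called in this comparison by edgeR (0 of 15529; 2070 had an unadjusted p under 0.05, and the smallest adjusted p was 0.241). DESeq2 called 237 genes, 224 higher and 13 lower, limma voom with sample quality weights called 3163, 1400 higher and 1763 lower, and the authors' deposited table called 3636, 1683 higher and 1953 lower. The 5 genes with the smallest p each had an adjusted p of 0.241: GOLGA6L9 (-0.75 ± 0.148), CD163L1 (0.55 ± 0.122), RAB2B (0.52 ± 0.116), TRIM21 (0.29 ± 0.0653) and SDHC (0.29 ± 0.0661). SDHC, a membrane subunit of succinate dehydrogenase, stood at 99.7 ± 8.61 CPM with naive and 122 ± 7.73 CPM with CYR61 BMDMs. In SDHC and in TRIM21, a ubiquitin ligase that binds antibodies in the cytosol, all 6 CYR61 BMDM libraries lay above every naive BMDM library. GOLGA6L9 belongs to a multi-copy family, CD163L1 and RAB2B overlap CD163 and TOX4, and SDHC overlaps CFAP126, so reads could be split or shared and these values are uncertain. With naive BMDM replicates 5 and 6 left out, 2808 genes were called, 1458 higher and 1350 lower, and 560 with the GC trend removed as well. Without naive BMDM replicate 6 alone, 89 were called; with the GC trend removed from all 18 libraries, 0 were called.

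No gene list was called between CYR61 and naive BMDMs. Glycolysis had an adjusted p of 0.310 with an estimated correlation; adjusted over the list alone, 5 members were higher, PKM, TPI1, ENO1 (0.22), GAPDH (0.23) and PFKM, the last named after its value was seen. Cholesterol synthesis had 14 of 23 members above 0 (adjusted p = 0.248). FDPS, the farnesyl diphosphate synthase (0.22), and NSDHL (0.25) were higher adjusted over the list alone, and DHCR7 (0.25) and FDFT1 (0.15) did not pass. Among the 30 genes of the S phase of the cell cycle, 18 lay above 0 (adjusted p = 0.310), and FEN1, the replication helicase subunits MCM7 (0.28) and MCM3 (0.19), GINS2 (0.15) and, named after its value was seen, CHAF1B were higher adjusted over the list alone. TPI1, ENO1, GAPDH, FDPS, DHCR7, FDFT1, FEN1, MCM7 and GINS2 overlap genes on the opposite strand.

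All 6 tested macrophage markers lay above 0 in this comparison (adjusted p = 0.420). CD68, a glycoprotein of lysosomes, stood at 38.4 ± 6.04 CPM with naive and 49.0 ± 3.25 CPM with CYR61 BMDMs (0.35 ± 0.0853; adjusted p = 0.241 over all genes), and was higher adjusted over the list alone. LAPTM5 stood at 0.07, CD14 at 0.68 and FCER1G at 0.20. The adjusted p was 0.911 for fibroblast and smooth muscle markers, 0.695 for epithelial markers and 0.911 for lymphatic endothelial markers. The median over the fibroblast and smooth muscle markers was -0.02 while the test pointed up. Of the always named genes, CXCL8 stood at -0.15, VCAM1 at -0.33, ICAM1 at 0.19, CCL2 at -0.0028, VEGFA at -0.06, KDR at -0.10, NOS3 at 0.08, CDH5 at 0.06, PECAM1 at 0.06, VWF at 0.17 and CCN1 at 0.01, and none passed. The sign of CCL2 turned with RLE size factors, the stricter filter, the replicate block, the GC trend removed, DESeq2, voom with quality weights and only the 12 libraries compared. That of CCN1 turned with library size only and with the GC trend removed. Those of LAPTM5, CXCL8 and CDH5 turned with the GC trend removed, and that of FCER1G in voom with quality weights.

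The third comparison set wells with CYR61-treated macrophages against BMDM-free wells. Here 616 genes were called, 298 higher and 318 lower. PLAT, the tissue plasminogen activator, stood at 250 ± 18.8 CPM in BMDM-free wells and 351 ± 40.8 CPM with CYR61 BMDMs (SD, n = 6; log2 fold change 0.49 ± 0.0771, adjusted p = 0.00738). SLC25A20, the carnitine carrier of mitochondria, stood at 19.1 ± 2.37 and 27.8 ± 3.30 CPM (0.54 ± 0.0997, adjusted p = 0.0185). EGR1, an immediate early transcription factor, stood at 13.3 ± 2.77 and 8.02 ± 1.40 CPM (-0.73 ± 0.141, adjusted p = 0.0185). For each of these 3 genes, all 6 CYR61 BMDM libraries lay beyond every BMDM-free library.

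The changes were small: the median absolute log2 fold change of the called genes was 0.35, and 9 reached an absolute value of 1. The largest increases among genes with at least 5 CPM were in TNFRSF14 (0.56, adjusted p = 0.0332), SLC25A20, TYRO3, a receptor tyrosine kinase (0.53), SLC4A11 (0.52), CYTL1 (0.51), TSPAN9 (0.50), SLC10A3 (0.50), PLAT, SHB (0.48) and ATXN7L3 (0.48). The largest decreases were in EGR1, ZNF518A (-0.65), ZNF770 (-0.64), ANGPT1, a ligand of the endothelial receptor TIE2 (-0.64 ± 0.159), C1orf56 (-0.63), ANKRD36C (-0.63 ± 0.0888, adjusted p = 0.00378), EPB41L4A (-0.63), ITGB8, an integrin subunit (-0.61), GLRX2 (-0.58) and HOXA3 (-0.56). ANKRD36C belongs to a multi-copy family, and TNFRSF14, TSPAN9, SHB, ATXN7L3, ZNF518A, ZNF770, C1orf56, EPB41L4A, ITGB8, GLRX2 and HOXA3 overlap other annotated genes, so their counts are uncertain. In the GENCODE 29 annotation PLAT (ENSG00000104368) lies on chromosome 8 from 42175233 to 42207724, and EGR1 (ENSG00000120738) on chromosome 5 from 138465490 to 138469315.

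**Figure D4:**
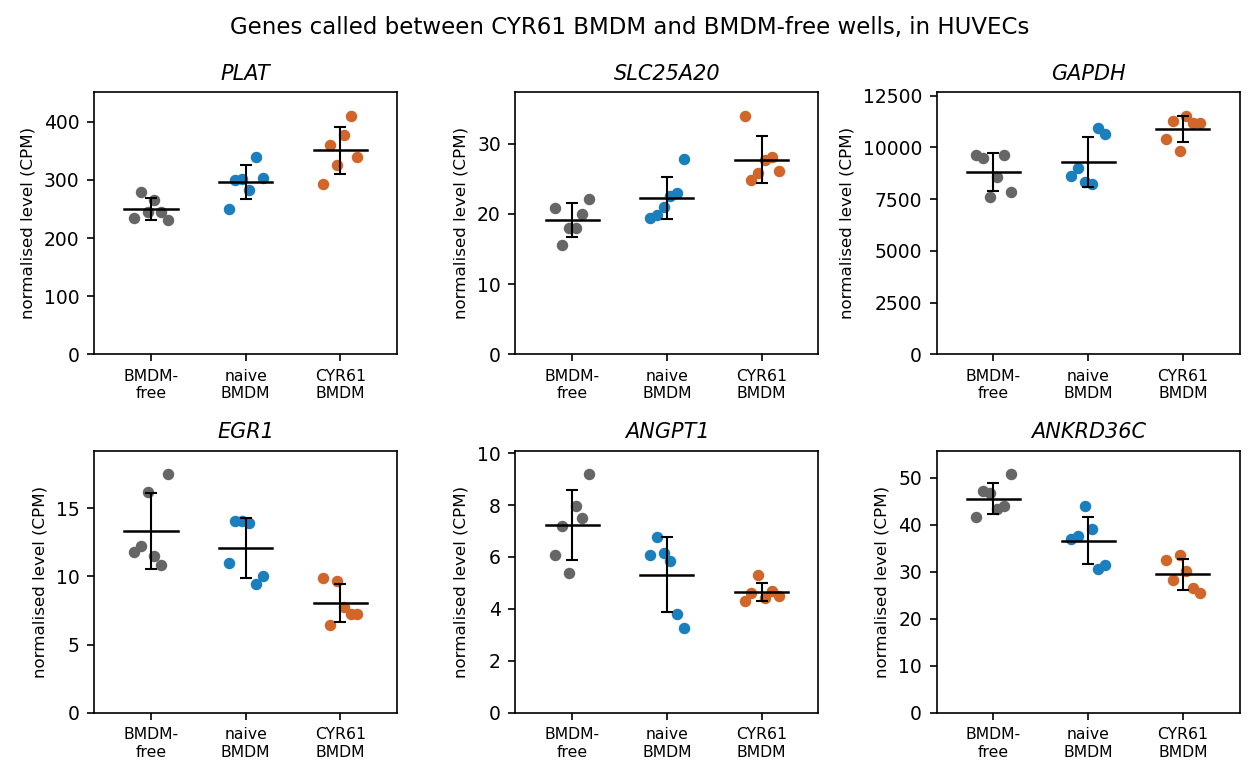
CPM of PLAT, SLC25A20, GAPDH, EGR1, ANGPT1 and ANKRD36C in each library (points) of the 3 groups on the horizontal axis, with group means and SD. PLAT has a mean of 250 CPM in BMDM-free libraries, 296 with naive BMDMs and 351 with CYR61 BMDMs, and EGR1 has means of 13.3, 12.1 and 8.02 CPM.

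The calls followed GC content and transcript length and moved with the libraries used. The median GC content of the transcripts was 55.7% for the genes called higher, 41.6% for those called lower and 48.8% for those not called. The median transcript length was 884 nt, 1582 nt and 1007 nt in the same order. Spearman's correlation of a library's deviations with length was 0.0445 ± 0.0707 in BMDM-free, 0.0243 ± 0.0624 in naive BMDM and -0.0682 ± 0.0338 in CYR61 BMDM libraries (SD, n = 6), and length was not corrected for. With each library's GC trend removed, 266 genes were called, 145 higher and 121 lower, and 158 of these were among the 616, in the same direction. TNFRSF14, TYRO3, SLC4A11, CYTL1, TSPAN9, SLC10A3, SHB, ATXN7L3, ZNF518A, ZNF770, ANGPT1 and HOXA3 were then no longer called, while PLAT (0.36), SLC25A20 (0.50), EGR1 (-0.88), ANKRD36C (-0.43), C1orf56 (-0.74), EPB41L4A (-0.51), ITGB8 (-0.40) and GLRX2 (-0.39) were. With naive BMDM replicates 5 and 6 left out of the shared estimate of the spread, 2360 genes were called, and 591 with the GC trend removed as well. Leaving out 1 library gave 837 genes (BMDM-free replicate 1), 224 (2), 16 (3), 16 (4), 1106 (5) and 12 (6), and 261 (CYR61 BMDM replicate 1), 19 (2), 1695 (3), 19 (4), 3 (5) and 16 (6); the 3 genes were PLAT, ANKRD36C and, named after its value was seen, TRIM16. The split into higher and lower was 457 and 267 with RLE size factors, 173 and 793 with library size only, and 1062 and 610 in DESeq2, against 298 and 318 here. The authors' deposited table called 3277 genes, 1680 higher and 1597 lower, of which 611 were among the 616.

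Genes of glycolysis rose with CYR61 BMDMs in 5 of 20 tested members, and 18 of 20 lay above 0. The 5 were PFKP, a phosphofructokinase (0.29), PKM (0.32), ENO1 (0.27), GAPDH (0.31) and TPI1 (0.25); adjusted over the list alone, 9 were higher and 1 lower. The list itself was not called (adjusted p = 0.352 with an estimated correlation), and after removal of the GC trend ENO1 stayed called while PFKP, PKM, GAPDH and TPI1 did not. In the S phase list MCM3 (0.21), MCM7 (0.30), GINS2 (0.18) and FEN1 (0.22) rose out of 30 tested, and adjusted over the list alone 4 were higher and 1 lower (list adjusted p = 0.391). None of these 4 was called once the GC trend was removed. PFKP, ENO1, GAPDH, TPI1, MCM7, GINS2 and FEN1 overlap other annotated genes.

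Genes of fibrinolysis and coagulation rose in 5 of 18 tested members: PLAT, the urokinase PLAU (0.39) and its receptor PLAUR (0.32), PROCR, the endothelial receptor of protein C (0.23), and ANXA2 (0.18), the last named after its value was seen. Adjusted over the list alone, 7 were higher and 1 lower, and the list was not called (adjusted p = 0.391). Among 23 proteases and inhibitors, the collagenase MMP1 (0.29) and the stromelysin MMP10 (0.31) rose, while MMP16 (-0.32) and CTSB (0.27) did not pass; 6 were higher and 3 lower adjusted over the list alone (list adjusted p = 0.391). PLAT, ANXA2, MMP1 and MMP10 stayed called without the GC trend, and PROCR, PLAUR and PLAU did not. MMP1 and MMP10 both overlap WTAPP1 on the opposite strand, and PROCR, PLAUR, PLAU, MMP16 and CTSB overlap other annotated genes.

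Genes of cholesterol synthesis fell in 5 of 23 tested members with CYR61 BMDMs, and 15 lay below 0. The 5 were HMGCS1 (-0.46), INSIG1 (-0.52), MSMO1 (-0.43), STARD4, a sterol carrier (-0.41), and, named after its value was seen, CYP51A1 (-0.27). Adjusted over the list alone, 6 were lower and 3 higher, and the list was not called (adjusted p = 0.391); its mean differed by -0.10 log2 CPM (exact permutation p = 0.00649, adjusted p = 0.107). HMGCS1, INSIG1, MSMO1 and STARD4 stayed called without the GC trend, and CYP51A1 (-0.08) did not. In the unfolded protein response, 3 of 19 members fell, the disulphide isomerase PDIA3 (-0.36), SEL1L (-0.39) and DNAJC3 (-0.27), the same 3 adjusted over the list alone; DNAJB9 stood at -0.32 and did not pass (list adjusted p = 0.564). PDIA3 and SEL1L stayed called without the GC trend and DNAJC3 did not. HMGCS1, STARD4, PDIA3, DNAJC3 and DNAJB9 overlap other annotated genes.

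NF-kB targets gave no call with CYR61 BMDMs: 17 of 23 lay above 0 (adjusted p = 0.391), 0 passed over all genes or adjusted over the list alone, and ICAM1 stood at 0.55 (adjusted p = 0.0949), CSF3 at 0.33, IL1A at 0.39 and NFKB1 at 0.21. All 6 macrophage markers lay above 0 (list adjusted p = 0.352). CD68 rose (0.31 ± 0.0852, adjusted p = 0.0430) and was not called once the GC trend was removed; LAPTM5 (0.16) was higher adjusted over the list alone, and CTSS stood at 0.23 and CD14 at 0.74. The adjusted p was 0.977 for fibroblast and smooth muscle markers, 0.397 for epithelial markers and 0.675 for lymphatic endothelial markers. Of the always named genes, VWF stood at 0.31 (adjusted p = 0.117), CCL2 at 0.21, NOS3 at 0.20, CDH5 at 0.11, PECAM1 at 0.07, VEGFA at 0.01, VCAM1 at -0.03, CCN1 at -0.04, KDR at -0.07 and CXCL8 at -0.13, and none passed. The sign of VEGFA turned with library size only, with the replicate block, with the GC trend removed and in voom with quality weights. That of VCAM1 turned with the GC trend removed and in voom with quality weights, and those of CXCL8 and CDH5 with the GC trend removed.

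Both comparisons with BMDM-free wells used the same 6 control libraries, and their calls were set side by side. No gene was called in both, since the first comparison called 0 genes against 616. Across genes, the log2 fold changes of the 2 comparisons had a covariance of 0.0308 (Pearson's r 0.508). Simulated unchanged groups against the same controls gave a mean covariance of 0.0248, between 0.0227 and 0.0271 over 20 simulations, and a mean r of 0.499. With the control libraries split into odd and even replicates, so that no control was shared, the covariance was 0.00628 and 0.0111. With the GC trend removed, it was 0.0229 with shared controls and 0.00200 and 0.00253 with split controls; the simulations were drawn with the spread before this correction and cannot judge these 3 values. HMGCS1 stood at -0.46 and INSIG1 at -0.53 with naive and -0.46 and -0.52 with CYR61 BMDMs. With the GC trend removed, 12 genes were called in the same direction in both comparisons, 3 higher and 9 lower. Independent lists would share 0.0373 and 0.0701 genes, a value that leaves out the shared controls, and the simulated unchanged groups shared 0, which is fixed where hardly any gene is called. With split controls 0 genes were called in both, where the comparison with naive BMDMs called 0 genes and that with CYR61 BMDMs 7 and 3. The 3 higher were LPXN, MMP1 and CDCP1.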

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

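The tests of the GC trend and of the top compartment's content were chosen only after the results were seen; the comparisons with other splits of the samples and the test of exchanged labels were written before, except that the first 3 splits of CYR61 against naive BMDMs, with the GC trend removed and with limma voom, had been seen when the share that decides was reworded.

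The lists of cholesterol synthesis genes and of fatty acid and LXR genes were lower beside naive BMDMs. Of 100 splits, 1, the real one, called as many lists (2 against at most 1 in any other). Even so, chance is not excluded. An exact permutation of each list's mean did not pass once adjusted over 99 tests (p = 0.00433 and 0.00649, adjusted p = 0.107 for both). The smallest p such a permutation can give is 0.0022, so a list could pass only if several lists lay near that value. This failure therefore says little about chance. A GC trend between libraries is argued against as the whole cause, since the cholesterol synthesis list stayed lower once it was removed (camera adjusted p = 1.37e-04). Over all 20 alternatives in camera or fry, most of which left the trend in, the adjusted p of this list lay between 1.01e-08 and 0.00585. Medium or other content of the top compartment that both BMDM groups share may also be the source. The list mean was lower with CYR61 BMDMs than in BMDM-free wells too (exact permutation p = 0.00649), though not past the threshold once adjusted (0.107). In fry the cholesterol synthesis list was called lower there (adjusted p = 0.0118). In camera it was not (adjusted p = 0.391, and 0.133 with the GC trend removed). No wells are labelled as holding that medium without cells, so the content and the cells cannot be told apart. The fatty acid and LXR list was no longer called with the stricter filter on low counts (adjusted p = 0.336), or without BMDM-free replicate 5 (adjusted p = 0.0514) or naive BMDM replicate 3 (0.0531). A response of HUVECs to the macrophages stays open as a hypothesis.

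Between CYR61 BMDM and BMDM-free wells, 616 genes were called. Few splits gave as many (2 of 100, the real one included), but chance is not excluded. The highest other gave 1878 and had the largest difference in GC trend (0.899, against 0.687 in the real split). This points to a structure of the samples. With the GC trend removed, 1 of 80 splits, the real one, reached 266 (highest other 58). Of the 616, 158 (25.6%) were still called in the same direction after the correction. Their median absolute log2 fold change went from 0.37 to 0.27, and which genes these are was set by the correction itself. The share that decides was set after the results were seen, and GC effects that the fitted curve does not capture are not covered. Within these limits, the trend is argued against as the whole cause of the 616 as a set. For the other 458 it stays open: their median log2 fold change in the original direction went from 0.34 to 0.17, a ratio of 0.506, while the median SE went from 0.0889 to 0.0629, so calls ended because the folds shrank more than the spread, and all 458 kept their sign. GC content and treatment cannot be told apart for these 458. Unchanged counts simulated with the trend gave 0 to 1 calls in 5 simulations. With changed genes added to such counts, 38 of 152 calls were unchanged genes, and 3 of 124 with the GC correction. Both kinds of counts were drawn with a spread that already held the trend. Transcript length was not corrected for. The 616 became 837, 224, 16, 16, 1106 and 12 without BMDM-free replicate 1, 2, 3, 4, 5 or 6. They became 261, 19, 1695, 19, 3 and 16 without CYR61 BMDM replicate 1, 2, 3, 4, 5 or 6.

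Between CYR61 and naive BMDMs, limma voom with sample quality weights called 3163 genes where edgeR called 0 (2070 at an unadjusted p under 0.05) and DESeq2 237. Chance cannot be excluded, since 8 of 60 splits gave as many (highest other 5143, the split with the largest difference in GC trend, 0.895), which points to a structure of the samples. That split differs from the real one only in exchanging naive BMDM replicate 6 and CYR61 BMDM replicate 3. With the GC trend removed it gave 257 genes in edgeR, where the real groups gave 0. Yet both libraries then lay on their own group's side of the middle between the groups, at -0.0806 and 0.234. A GC trend stays open: with it removed 0 of the 3163 stayed called, as the median log2 fold change in the original direction went from 0.30 to 0.13 and the median SE from 0.0804 to 0.0649, but the sample weights were estimated again, and with the weights of the uncorrected fit 551 stayed called, while the new weights without the correction left 0. For exchanged labels of naive BMDM replicates 5 and 6, the rule written before asked that at least 1 of them lie nearer the CYR61 group. Neither did, at -0.204 and -0.0806, so by that rule an exchange is argued against. Both lay within about 1 SD of the naive positions (0.190) from the middle between the groups. That margin was not part of the rule, and only with it does an exchange stay open. CYR61 BMDM replicate 1 (-0.483) lay nearer the naive group. The naive BMDM library nearer the CYR61 group was replicate 3 (0.0369), which gives no support to an exchange of replicates 5 and 6. Without these 2 libraries edgeR called 2808 genes (89 without replicate 6 alone), and 560 with the GC trend removed; the libraries were left out after their values were seen, and a difference between the treatments stays open.

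Where 0 genes or lists were called, every split gives as many. This held for genes between naive BMDM and BMDM-free wells (100 of 100 splits, highest other 432), for genes between CYR61 and naive BMDMs (100 of 100, highest other 4318; 80 of 80 with the GC trend removed, highest other 257), and for lists in the comparisons of CYR61 BMDMs with naive BMDMs (100 of 100, highest other 0) and with BMDM-free wells (100 of 100, highest other 2). The splits that called 432, 4318 and 257 genes point to a structure of the samples. For the 13 genes called between naive BMDM and BMDM-free wells with the GC trend removed, 1 of 80 splits, the real one, gave as many (highest other 2). Chance is thus unlikely for this count but not excluded, since the correction was chosen after seeing the data.

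Single libraries far from the other 5 of their group, by the gap to the nearest divided by the group's range, numbered 18 of 348 groups of values, and chance gives 17.4. In BMDM-free wells these were CXCL8 in replicate 6 (137 CPM, the others 88.3 to 98.9), VEGFA in replicate 3 (0.662 CPM), SLC10A3 in replicate 1 (10.4 CPM) and SHB in replicate 6 (4.23 CPM). With naive BMDMs they were ABI3BP in replicate 3 (17.1 CPM), GOLGA6L9 in replicate 4 (4.02 CPM), and in replicate 5 LPCAT3 (16.8 CPM), ZNF518A (5.16 CPM) and MMP10 (20.2 CPM). With CYR61 BMDMs, replicate 1 had 30039 genes detected (the others 23770 to 24999), 3.33% of counts from mitochondrially encoded genes, SLC25A20 at 34.0 CPM and PLAU at 12.9 CPM. CYR61 BMDM replicate 3 had a GC trend of -0.458, ADAM15 at 35.1 CPM, ZNF770 at 18.6 CPM, GLRX2 at 26.8 CPM and ITGA2 at 120.3 CPM.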

How the results depend on the processing

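The GC correction, voom without weights or with the GC correction, and the fits without several libraries were chosen after seeing the data; most causes of a moved count were not tested. Naive BMDM against BMDM-free wells gave 0 genes, but 8 without a filter, 6 in DESeq2, 2 in voom with quality weights (4 with GC correction), 13 with GC correction, and 0 to 1 with 1 library left out. CYR61 against naive BMDMs gave 0, but 57 without a filter, 237 in DESeq2, 3163 in voom with quality weights, and 0 to 89 with 1 library left out. CYR61 BMDM against BMDM-free wells gave 616, but 9 at an absolute log2 fold change of at least 1, 966 with library size only, 1252 with the stricter filter, 1672 in DESeq2, 2950 in voom with quality weights (370 with GC correction), 1881 with only the 12 libraries compared, 266 with GC correction, and 3 to 1695 with 1 library left out; RLE gave 724 and voom without weights 495.

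Without naive BMDM replicates 5 and 6 the 3 counts were 0, 2808 and 2360 (GC-corrected 2, 560 and 591). Without CYR61 BMDM replicate 1 too, they were 0, 2352 and 1968 (2, 552 and 690), and without CYR61 BMDM replicates 1 and 2 too, 0, 1474 and 1152 (3, 336 and 409). The replicate block gave 0, 0 and 812 genes and, with GC correction, 7, 0 and 137; the numbers share no more than a name, as same-numbered libraries correlated between -0.144 and 0.204 over 18 pairs, 2 of them over 0.1, and 2 libraries correlated best with their own number.

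The lists called between naive BMDM and BMDM-free wells were 2, but 1 with the stricter filter (30 lists), 4 with a preset correlation, where cholesterol and fatty acid genes also held with an estimated one and NF-kB and ATF4 genes did not, and 4 in fry. For CYR61 against naive BMDMs the preset correlation called 5 lists against 0, and against BMDM-free wells 5 against 0, with 5 in fry; none of these held with an estimated correlation. The overlap of calls was 0, but 7 without a filter, 6 in DESeq2 and 12 with GC correction.

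Of the values of single genes under other settings, 1089 kept direction and side of the threshold, 118 passed newly, 40 no longer passed and 26 changed sign. None of the sign changes was in a called gene. CCL2 between CYR61 and naive BMDMs stood at 0.0263 with RLE, 0.0175 with the stricter filter, 0.00577 with the block, 0.0297 with GC correction, 0.0294 in DESeq2, 0.00996 in voom with quality weights and 0.0306 with 12 libraries. With library size only, CXCL8 (-0.00357), KDR (-0.000169) and PECAM1 (-0.00871) changed sign for naive BMDMs, CCN1 (-0.00865) between CYR61 and naive BMDMs, and VEGFA (-0.0256) for CYR61 BMDMs against BMDM-free wells. VEGFA there stood at -0.0027 with the block, -0.14 with GC correction and -0.11 in voom with quality weights. With GC correction NOS3 (-0.00933) changed sign for naive BMDMs, LAPTM5 (-0.0366), CCN1 (-0.10), CXCL8 (0.0254) and CDH5 (-0.0267) between CYR61 and naive BMDMs, and VCAM1 (0.16), CXCL8 (0.11) and CDH5 (-0.0263) for CYR61 BMDMs against BMDM-free wells. In voom with quality weights VWF stood at -0.0432 for naive BMDMs, FCER1G at -0.0296 between CYR61 and naive BMDMs and VCAM1 at 0.0125 for CYR61 BMDMs against BMDM-free wells. Depth and spread limited small changes: of the smallest change simulated, 16% to 20% of genes were called.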

Other observations

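The lists described here were chosen after seeing the results. Between CYR61 BMDM and BMDM-free wells, 2 metallothioneins, which bind zinc and copper, rose out of 8 tested members of their list: MT1E (log2 fold change 0.35) and MT2A (0.34), while MT1X stood at 0.21 and the zinc transporter SLC39A10 at -0.32 (list adjusted p = 0.397; adjusted over the list alone 3 higher and 1 lower). Of the 26 tested genes of the amino acid response that depends on ATF4, 18 lay above 0; PCK2 (0.43), GPT2 (0.47) and SHMT2 (0.28) rose and SLC7A11 (-0.36) fell, and adjusted over the list alone 5 were higher and 2 lower (list adjusted p = 0.391). In the fatty acid and LXR list SCD (-0.33) fell and PLIN2 (0.26) rose, and ANGPTL4 (0.75) and FASN (-0.53) did not pass (list adjusted p = 0.397; adjusted over the list alone 2 higher and 3 lower). In the list of G2 phase and mitosis 19 of 30 lay below 0, and CENPF (-0.42), a kinetochore protein, and ASPM (-0.50), a spindle pole protein, fell, while AURKB (0.25) and CDC20 (0.43) did not pass (list adjusted p = 0.802; adjusted over the list alone 4 higher and 3 lower). In the list of cell junctions TJP1 (-0.34), a scaffold of tight junctions, fell, and OCLN (-0.97), MARVELD2 (-0.43) and GJA1 (-0.26) did not pass (list adjusted p = 0.651; adjusted over the list alone 2 higher and 6 lower). With the GC trend removed, MT1E, MT2A, CENPF, ASPM, TJP1, SCD and PLIN2 stayed called, and none of the ATF4 genes did. MT1X, SLC39A10, PCK2, SHMT2, SLC7A11, ANGPTL4, CENPF, ASPM, TJP1 and OCLN overlap other annotated genes, so their counts are uncertain.

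With the GC trend removed, a correction chosen after seeing the data, the genes called between naive BMDM and BMDM-free wells included HMOX1, the heme oxygenase (-0.35, adjusted p = 0.0133), ITGA2, an integrin subunit for collagen (-0.22, adjusted p = 0.0374) and STAB1, a scavenger receptor (0.30, adjusted p = 0.0133). These genes were named after their values were seen, and ITGA2 and STAB1 overlap other genes. In the same fit HMOX1 stood at -0.30 and ITGA2 at -0.22 with CYR61 BMDMs against BMDM-free wells and were called there too, while STAB1 (0.11) was not. Both comparisons used the same 6 control libraries. With the controls split between them, 0 genes were called in both. That count was fixed, since the comparison with naive BMDMs then called 0 genes, so it cannot tell whether the sharing came from the controls.

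ACTB, which encodes beta-actin, took between 0.488% and 2.68% of the counts of a library, while ACTG1, which encodes gamma-actin, took between 0.548% and 0.731%. Over the 18 libraries, 146 of 9559 genes had a Pearson's r above 0.9 with ACTB; this was noticed in the data. The SD of the log2 CPM of ACTB over the libraries was 0.751 before and 0.696 after the GC trend was removed. The median GC content of the 146 genes was 54.7%, against 48.0% over the genes compared. The 26 genes named as ACTB pseudogenes or POTE came to at most 4.30 CPM together in a library, and no other explanation was tested.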
